A study of Mus musculus with 4 samples.

How the data were processed

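Transcript levels were measured in heart ventricles of mouse embryos on 4 Affymetrix MOE430v2 arrays, with 2 arrays from wild-type embryos (WT) and 2 from littermates lacking HDAC2 (KO). Per the labels, the embryos were at embryonic day 17.5, the strain was a cross of C57BL/6 and SV129, each WT array took RNA from a pool of 2 animals and each KO array from a pool of 3, and 6 µg of total RNA was labelled with biotin for every array. Groups and replicate numbers were taken from the sample titles. The source field of both KO samples also carries the abbreviation for wild type, so the Hdac2 probe sets were read on every array first. The labels do not say whether animals were shared between pools, and pool size differs with genotype. The p-values therefore measure only the spread between these pools, which may be partly technical.

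The deposited signal of each probe set is an intensity on a linear scale, 1 colour per array, made with MAS5 per the submitters' processing notes. The version of MAS5 is not given in the sources used here. The deposited signals of all 4 arrays had the same 2%-trimmed mean, 150, so the scaling planned for the fit changed nothing. Per the file headers, each probe set also has a detection p-value with a Present, Marginal or Absent call, a signal log ratio and a change p-value against a baseline array. The deposited signal log ratio is on a log2 scale, and the baseline array is not given in the sources used here. The change p-value was not used here. The deposited table of values for the whole series held the same signals as the array files.

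Of 45101 probe sets, 64 controls were left out. Gene names came from the platform's annotation, in which 34945 of the other 45037 probe sets name 1 gene, 932 name several and 9160 are not listed. No gene was named from a probe set with several. Symbols were updated through the gene identifier with a table of mouse genes of assembly GRCm38.p6, which held 34741 of the 34945. The genome build behind the platform annotation is not given in the sources used here, so no coordinates are printed and the table served only for names and for which genes lie near each other.

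Probe sets called Present on both arrays of at least 1 group were tested, 19065 in all, of which 16669 name 1 of 10184 genes. The log2 signal was fitted with limma 3.58.1 (lmFit, then eBayes with a variance trend on mean signal) in R 4.3.3, with genotype as the sole factor and all 4 arrays in the fit. The 4 signals of 0 were set to 0.1 before taking logs, a step that was not in the planned design. Differences are KO minus WT on the log2 scale, ± the moderated standard error (SE), with n = 2 arrays per group. The p-values are two-sided and were adjusted by the Benjamini-Hochberg method over all probe sets tested, with 0.05 as the threshold. A second, exploratory count took probe sets at unadjusted p under 0.01 and at least 1.5-fold, and such probe sets are not called changed. Where a group had no Present call on either array, the fold is given as "at least": the brighter group's mean log2 signal is set against the mean of, per array, the higher of the dim probe set's own signal and the lowest signal called Present on that array. This equals the fitted fold where the dim signals lie above those lowest signals, and elsewhere the fitted difference is larger and is no bound. With 2 arrays per group, the number of arrays limits the precision.

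The following were chosen before the data were examined: the fit, the filter, the rule for naming genes, the alternatives other than those named as added, and 36 gene lists with 932 memberships, 881 of which matched a gene on the array. The genes named are a set of fixed genes of cardiac growth and of HDAC2 biology, the sex-linked genes, the 12 genes with the largest difference in each direction among those past the threshold (1 probe set per gene, the one with the smallest p, predicted transcripts left out), and in each list the members past 0.05 when adjusted over the list alone with at most 4 others. Genes outside that rule are said to be chosen after their values were seen. Each list with at least 5 tested genes was tested with limma's camera at a preset correlation between genes of 0.01, on the brightest tested probe set of each gene, and p was adjusted over the 31 lists tested. Camera with an estimated correlation and limma's fry, which does not compare a list with other genes, were alternatives. With 4 arrays, the estimated correlation leaves camera few residual degrees of freedom and so little power. Genes within 20 Mb of Hdac2 on its chromosome were compared with random draws from all tested genes of known location by a two-sided permutation test of the mean absolute moderated t statistic, with 100000 resamples.

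The alternatives were quantile normalization, centring on the median of probe sets Present on all 4 arrays, offsets of 16 and 64 added before the log, no filter on detection, Present on all 4 arrays, no variance trend, a robust variance prior, the series' table of values, each array left out in turn, the title's number as a block, probe sets ending in _x_at or _s_at left out, the mean of all probe sets of a gene, and windows of 10 and 40 Mb around Hdac2. Added after the data were seen were 2 fits of the signal log ratio, the brightest probe set of each gene alone, and the share of genes near Hdac2 at unadjusted p under 0.01 without Hdac2 itself. Lists of bone, cartilage, tendon, epidermis and further muscle markers were also added then. So was leaving out the genes of the skeletal muscle list and of these added lists other than epidermis. With an array left out, the group with 1 array is assumed to vary like the other.

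The fit was tested on simulated data, in 20 simulations with the 19065 probe sets of this comparison, of which 200 were changed in each. It recovered 79.7% of 2-fold and 97.8% of 4-fold changes, none in the wrong direction, and 7.26% of its calls were unchanged probe sets, above the nominal 5%. The noise was normal, with the moderated variances of the same fit, so real changes may be recovered less often. A shifted list was called by camera in all 20 simulations and no unchanged list was. The simulated probe sets varied independently and the lists were drawn at random. The simulations therefore cannot show how the preset correlation fares with correlated genes, such as those of oxidative phosphorylation (estimated correlation 0.25).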

Results

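Hdac2 encodes a class I histone deacetylase studied for its part in the growth of the heart muscle, and the comparison asks which transcripts differ in the ventricle of late mouse embryos that lack it. The 2 WT and 2 KO arrays detected similar shares of their probe sets, with Present calls on 43.1% and 42.4% of probe sets in WT and on 43.1% and 43.7% in KO. Across the 19065 probe sets tested, which are not independent of each other, log2 signals correlated at r = 0.983 between the WT arrays and r = 0.981 between the KO arrays, against 0.965 to 0.972 between a WT and a KO array. The signal of the 3' control probe set of actin over its 5' probe set, a measure of RNA length, was 1.85 and 2.32 in WT and 2.75 and 2.42 in KO. The same ratio for Gapdh was 0.844 and 0.949 in WT and 1.18 and 1.01 in KO.

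Hdac2 itself fell on both KO arrays. Its brightest probe set, 1445684_s_at, had signals of 1189 and 1421 in WT and 31.4 and 21.0 in KO, at least 50.6-fold lower, with no Present call in KO. Probe set 1449080_at had signals of 451 and 425 in WT and 0.3 and 0.2 in KO, at least 71.8-fold lower. A dimmer Hdac2 probe set, 1439704_at, read 48.8 and 43.2 in WT against 24.3 and 12 in KO and did not pass the test (at least 2.69-fold, adjusted p = 0.123 in limma). The brightest probe set differed by -5.66 ± 0.21 (adjusted p = 2.32e-09 in limma). The Hdac2 transcript level, brightest probe set, differed by -5.40 with adjusted p = 0.0771 when the signal log ratio took the place of the log2 signal. Where the mutation lies relative to these probe sets is not given in the sources used here.

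**Figure D1:**
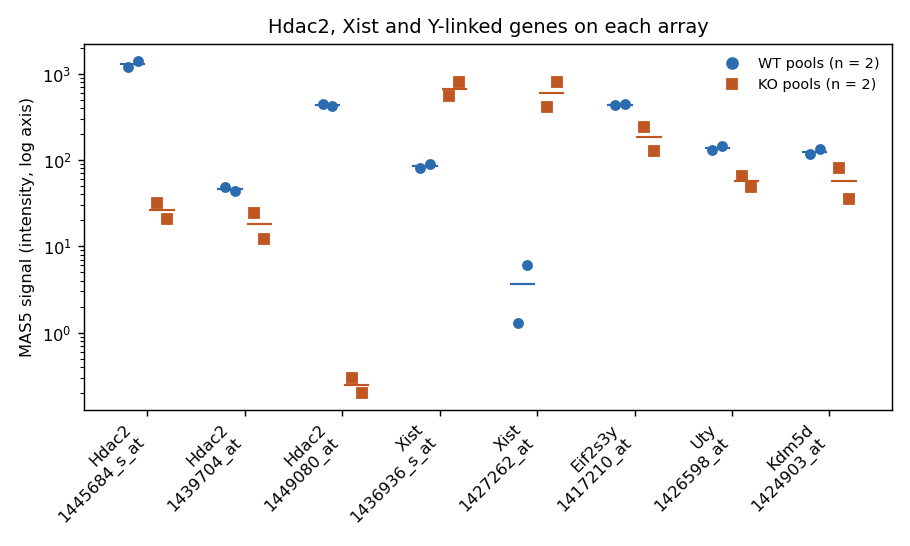
MAS5 signal (log axis) of the Hdac2, Xist and Y-linked probe sets on each array, with circles for the 2 WT pools, squares for the 2 KO pools and short lines for group means. Hdac2 1445684_s_at lies at 1189 and 1421 in WT and at 31.4 and 21.0 in KO, and Xist and the Y-linked genes also separate the groups.

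Transcripts of the sex chromosomes differed between the groups as well. Xist, the noncoding RNA that coats the inactive X chromosome, rose from 80.5 and 90.1 in WT to 548 and 794 in KO at probe set 1436936_s_at (7.74-fold, adjusted p = 8.10e-07), and at least 108-fold at 1427262_at. Eif2s3y, the Y-linked copy of a translation initiation factor, fell from 431 and 449 to 240 and 126 (adjusted p = 0.0105). Uty, a Y-linked relative of a histone demethylase, fell from 132 and 146 to 66.0 and 48.9 at 1426598_at (adjusted p = 0.0138). Kdm5d, a Y-linked histone demethylase, read 117 and 133 in WT and 80.4 and 35.3 in KO (-1.23 ± 0.32, adjusted p = 0.0883). Of 4 sex-linked genes tested, 1 was higher and 2 were lower over all probe sets, and 1 was higher and 3 were lower adjusted over the list alone. The sex of the embryos is not given in the sources used here. The Uty call was lost without WT replicate 2 (adjusted p = 0.0540) and without KO replicate 2 (adjusted p = 0.0541).

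Genes of fast and embryonic skeletal muscle fell together in KO, the list with the smallest p in camera (adjusted p = 7.71e-38, but 0.346 with an estimated correlation). Tnnc2, the calcium-binding troponin subunit of fast muscle, fell from 2418 and 2161 to 5.6 and 34.6, at least 156-fold (66.1-fold without KO replicate 1). Tnnt3, fast troponin T, fell from 1153 and 1269 to 21.6 and 21.7, at least 55.9-fold, and Mylpf, a fast regulatory myosin light chain, fell from 2972 and 2654 to 80.4 and 62.5, at least 39.6-fold. The perinatal and embryonic myosin heavy chains Myh8 and Myh3 fell by 4.64 and 4.47 on the log2 scale, and the giant thin-filament protein gene Neb fell at least 13.1-fold. Myh1, Myl1, Klhl41 and Tnni2 fell too. Of the 13 tested genes of this list, 10 fell, none rose, and 12 were lower adjusted over the list alone, the additional ones being Actn3 (at least 6.74-fold, adjusted p = 0.0506) and Chrna1 (at least 1.70-fold, adjusted p = 0.240). Ckm, the muscle creatine kinase that heart muscle also makes, had a log2 difference of -0.028 ± 0.081 (adjusted p = 0.903), and its sign turned with quantile normalization (0.023) and without KO replicate 1 (0.028). All 13 genes were Present on both WT arrays and 5 of them on both KO arrays. The list's median log2 difference was -4.03, or -3.71 with the 7 members that had no Present call in KO at their bound, and fry gave an adjusted p = 0.0351. Tnnc2 lost its call with a robust variance prior (adjusted p = 0.206).

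**Figure D2:**
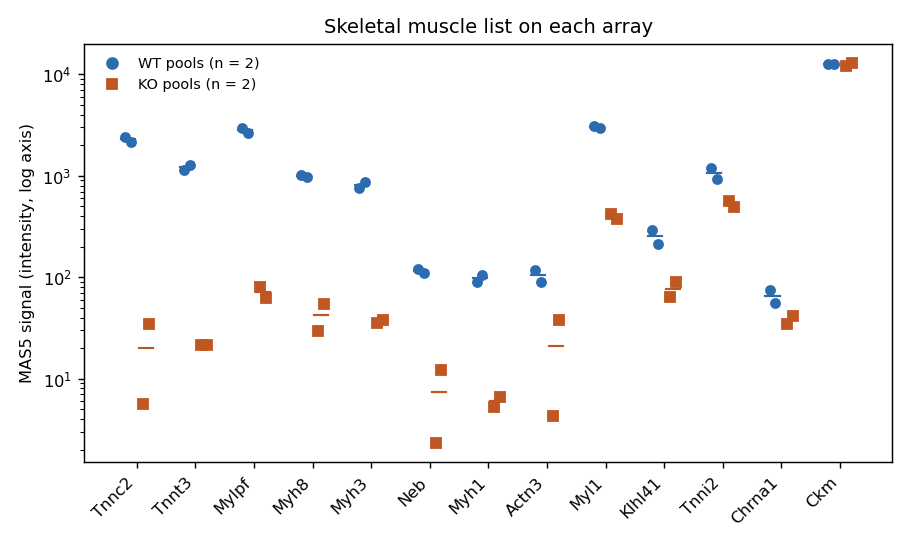
MAS5 signal (log axis) of the brightest probe set of each tested skeletal muscle gene, with circles for the 2 WT pools, squares for the 2 KO pools and short lines for group means. Both KO pools lie below both WT pools at every gene shown except Ckm, where the log2 difference was -0.028.

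Outside that list, the genes with the largest falls included 3 that are known from mineralised tissue. Ibsp, an acidic matrix protein of bone, fell at least 32.6-fold at 1417484_at, from 206 and 192 to 1.1 and 0.2, and at least 4.21-fold at 1417485_at, from 48.9 and 53.6 to 8.7 and 17 (adjusted p = 0.0319). Dmp1, a matrix protein of osteocytes, fell at least 9.89-fold, and Mmp13, a collagenase of growing bone and cartilage, fell at least 15.0-fold. Atp1b4, a muscle protein related to the beta subunit of the sodium pump, fell at least 44.2-fold (24.8-fold without KO replicate 2), and Myot, a protein of the muscle Z-disc, fell from 250 and 264 to 23.2 and 7.9. All of these had no Present call in KO and were detected on both WT arrays, and the skeletal muscle list moved in the same direction by a median of -4.03. The Dmp1 call was lost without WT replicate 1 (adjusted p = 0.0982) and without WT replicate 2 (adjusted p = 0.0911), and that of Ibsp 1417485_at without WT replicate 1 (adjusted p = 0.108), without WT replicate 2 (adjusted p = 0.117) and with quantile normalization (adjusted p = 0.0634).

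Across the array, 256 of the 19065 probe sets tested passed the adjusted threshold in limma, 73 higher and 183 lower in KO. They named 203 genes, 63 higher and 140 lower, and none in both directions. At every one of the 256, both KO arrays lay beyond both WT arrays. Of the called probe sets, 22 were at least 2-fold higher and 100 at least 2-fold lower. The exploratory count was 193 higher and 433 lower, and 2959 probe sets had an unadjusted p under 0.05. Without the genes of the skeletal muscle list and of the added muscle, bone, cartilage and tendon lists, 68 probe sets were higher and 152 lower. Other genes of these tissues, such as Acta1, Atp1b4, Fhl1 and Col1a1, are not on those lists and stayed in. The counts rested on the variance trend, without which 4 were higher and 19 lower, and on the filter on detection, without which 7 were higher and 30 lower. They were 222 and 428 without KO replicate 1, 53 and 110 without WT replicate 1 and 48 and 184 without KO replicate 2, and the signal log ratio gave 0 and 0 (111 and 255 at the exploratory threshold), or 0 and 1 with its variance trend on the log2 signal.

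**Figure D3:**
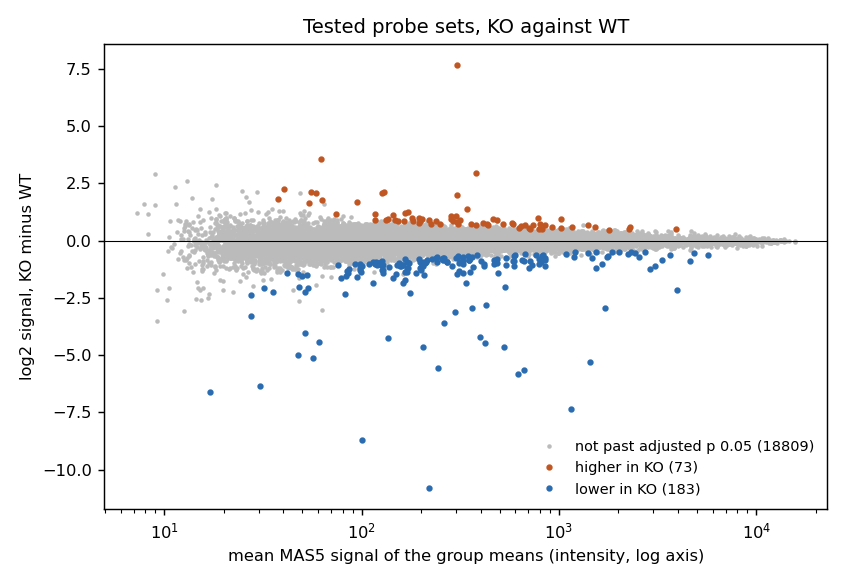
Difference in log2 signal (KO minus WT) of every tested probe set against its mean MAS5 signal (log axis), with grey for probe sets not past adjusted p 0.05, orange for those higher and blue for those lower in KO. The 73 higher and 183 lower probe sets include falls of over 5 log2 units, among them Hdac2, Tnnc2, Tnnt3 and Mylpf.

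Besides Xist, the genes with the largest rises were a mixed group. Cap1, an actin-regulating protein, rose at both of its probe sets, from 122 and 121 to 446 and 528 at 1417461_at (1.99 ± 0.16, adjusted p = 1.02e-05). Gstt2, a glutathione transferase, rose at least 4.39-fold, Glrb, the beta subunit of the glycine receptor, at least 4.21-fold at 1459850_x_at (its dimmer 1422504_at, at 0.94 ± 0.49, did not pass, adjusted p = 0.376), and Hbb-y, an embryonic beta-globin, at least 4.83-fold at 1436823_x_at. Amacr, a racemase of branched-chain fatty acid breakdown, rose 3.23-fold, and Atmin, a cofactor of the ATM kinase, rose at least 3.18-fold. Tank, an adaptor of innate immune signalling, rose 2.39-fold and Atpsckmt, a methyltransferase acting on ATP synthase, at least 2.26-fold. Serinc3, a membrane protein that adds serine to lipids, rose at least 11.8-fold at the dim probe set 1434548_at (6.85-fold without WT replicate 1), while its other 3 probe sets did not pass, the brightest at 0.23 ± 0.10. Limd1, a LIM-domain protein, rose by 1.40 ± 0.15 at 1422731_at, with 0.47 ± 0.15 and adjusted p = 0.151 at its brighter probe set. Rpl37a, a ribosomal protein, rose by 2.10 ± 0.21 at 1416218_x_at, with 0.11 ± 0.089 at its brightest probe set, and the first probe set's difference turned to -0.40 in the signal log ratio. One array left out ended the calls of Gstt2 (adjusted p = 0.0617), Amacr (0.101), Tank (0.201), Atmin (0.104) and Atpsckmt (0.113) without KO replicate 2, of Tank (0.0593), Atmin (0.101) and Atpsckmt (0.111) without WT replicate 2, and of Atmin (0.0682), Atpsckmt (0.0675) and Hbb-y at 1436823_x_at (0.0566) without KO replicate 1. Tank also lost its call with a robust variance prior (adjusted p = 0.0578).

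Most of the genes that mark cardiac growth and hypertrophy did not pass the test. Acta1, the skeletal alpha-actin that the fetal heart also makes, fell from 6453 and 6524 to 1510 and 1393, 4.47-fold (-2.16 ± 0.095, adjusted p = 1.04e-08). Fhl1, a LIM-domain protein of heart and skeletal muscle, fell by 0.49 ± 0.10 (adjusted p = 0.0261). Neither natriuretic peptide gene passed the test, with differences of 0.12 ± 0.10 for Nppa (adjusted p = 0.620) and -0.026 ± 0.094 for Nppb (adjusted p = 0.924). The same held for the myosin heavy chain Myh7 (-0.040 ± 0.079), the stress-responsive Ankrd1 (-0.095 ± 0.092) and Hopx, a homeodomain partner of HDAC2 (-0.14 ± 0.088). Myh6, the alpha myosin heavy chain, stood at -0.079 ± 0.081 at its brightest probe set and fell by 1.45 ± 0.25 at the dim 1417729_at (adjusted p = 0.00977). In the list of fetal and hypertrophic cardiac genes, Acta1 and Fhl1 were the 2 of 20 tested genes that fell, also adjusted over the list alone, and camera gave an adjusted p = 0.0818 (0.688 with an estimated correlation), while the list passed without WT replicate 1, WT replicate 2 or KO replicate 2. Acta1 and Fhl1 are genes of skeletal muscle too, and the skeletal muscle list moved the same way by a median of -4.03. The calls of Fhl1 and of Myh6 at 1417729_at were lost without WT replicate 1 (adjusted p = 0.277 and 0.0888), and the near-zero differences of Nppa, Nppb and Myh7 turned sign with an array left out.

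Inpp5f, an inositol polyphosphate phosphatase set between HDAC2 and the Akt pathway in studies of hypertrophy, read 107 and 146 in WT and 177 and 172 in KO. The difference of 0.48 ± 0.20 did not pass (adjusted p = 0.274, and 0.0951 adjusted over the list alone of fixed genes), and its dimmer probe sets stood at 0.36 ± 0.51 and 0.052 ± 0.47. No member of the 19 inositol phosphatases tested passed in limma, 0 over all probe sets and 0 adjusted over the list alone, with Mtmr1, a phosphoinositide phosphatase, closest at 0.66 ± 0.20 (adjusted p = 0.133), and the list did not pass (adjusted p = 0.614). At unadjusted p under 0.05 there were 4, all higher. The brightest probe sets of the kinases Akt1 (-0.14 ± 0.11, adjusted p = 0.599) and Gsk3b (0.17 ± 0.14, adjusted p = 0.586) did not pass either, while the dimmer Akt1 probe set 1425711_a_at fell by 1.48 ± 0.23 (adjusted p = 0.00458). Among 23 genes of PI3K, Akt and Gsk3 signalling tested, 0 passed over all probe sets and 0 adjusted over the list alone, with 4 at unadjusted p under 0.05 (list adjusted p = 0.858). Cyclin D1, Ccnd1, stood at -0.040 ± 0.12 (adjusted p = 0.905), a sign that turned without KO replicate 1 (0.066) and in the signal log ratio (0.05).

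Other histone deacetylases and their partners showed no difference past the threshold. Hdac1, the closest relative of Hdac2, stood at -0.30 ± 0.13 (adjusted p = 0.275) and Hdac3 at -0.078 ± 0.14 (adjusted p = 0.836), the latter turning to 0.084 without KO replicate 2. Of the 9 tested members of the histone deacetylase list, which includes Hdac11 of class IV, Hdac2 alone fell, over all probe sets and adjusted over the list alone. Hdac9 stood at 0.40 ± 0.15 (adjusted p = 0.222). The list had an adjusted p = 0.0818 in camera (0.688 with an estimated correlation), but it holds Hdac2 itself and was not tested without it. None of the 26 tested subunits of the Sin3, NuRD and CoREST corepressor complexes passed over all probe sets or adjusted over the list alone, with Sin3b closest at 0.30 ± 0.11 and 4 at unadjusted p under 0.05 (list adjusted p = 0.920).

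Oxidative phosphorylation genes were lower as a list with camera's preset correlation only, and no member passed. Of 45 tested, 34 had a negative difference and 11 a positive one, with a median of -0.079, and the calls were 0 over all probe sets and 0 adjusted over the list alone in limma, with 4 at unadjusted p under 0.05. The members with the smallest p were Cox7a1, a muscle subunit of cytochrome oxidase (-0.36 ± 0.11), Cyc1, cytochrome c1 (-0.23 ± 0.080), and Cox8b, another muscle subunit of the oxidase (-0.29 ± 0.10), and the skeletal muscle list moved the same way by a median of -4.03. Camera gave the list an adjusted p = 0.00162, against an adjusted p = 0.701 with an estimated correlation and 0.378 with fry. The estimated correlation leaves camera little power on 4 arrays, so its 0.701 does not settle the list. The list: oxidative phosphorylation also lost its call without WT replicate 1 (adjusted p = 0.251), without KO replicate 1 (adjusted p = 0.171) and without a variance trend (adjusted p = 0.0701), with a median of -0.047 and -0.033 in the first 2 cases.

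Genes of the other metabolic pathways and of the contractile machinery did not pass as lists. In fatty acid oxidation (31 tested, adjusted p = 0.752), Cpt2, a carnitine transferase of the mitochondrial inner membrane (0.57 ± 0.13, adjusted p = 0.0507), and Decr1, a reductase for unsaturated fatty acids (0.42 ± 0.11, adjusted p = 0.0892), were higher adjusted over the list alone and no member passed over all probe sets, with 8 at unadjusted p under 0.05. In glycolysis and hypoxia response (32 tested, adjusted p = 0.681), the glucose transporter Slc2a4 (-0.53 ± 0.13, adjusted p = 0.0628) was lower and the prolyl hydroxylase P4ha1 (0.56 ± 0.14, adjusted p = 0.0672) higher adjusted over the list alone, again with no member past the threshold over all probe sets and 7 at unadjusted p under 0.05. Sarcomere genes (29 tested, median -0.038, adjusted p = 0.0568) had no member past the threshold and 5 at unadjusted p under 0.05, and Des, the muscle intermediate filament (-0.37 ± 0.10), and Myom2, an M-band protein (-0.35 ± 0.10), were lower adjusted over the list alone. Des was also the 1 lower member of the 17 tested serum response factor targets and smooth muscle genes adjusted over the list alone (0 over all probe sets, 5 at unadjusted p under 0.05, list adjusted p = 0.278). Sln, a small inhibitor of the calcium pump, fell by 0.84 ± 0.17 (adjusted p = 0.0249) and was the 1 called gene among 32 genes of calcium handling and ion channels, also adjusted over the list alone (list adjusted p = 0.184). Whether the fall of Sln shares a source with that of the skeletal muscle list (median -4.03) was not tested.

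Col1a1 and Col1a2, which encode the chains of type I collagen, fell by 0.73 ± 0.10 and 0.55 ± 0.10 (adjusted p = 0.00199 and 0.0118), and Bgn, a small matrix proteoglycan, was lower adjusted over the list alone (-0.66 ± 0.16, adjusted p = 0.0737). Lox, which cross-links collagen (-0.47 ± 0.15), and Pdgfra, a receptor of fibroblasts (0.52 ± 0.17), did not pass. Of 33 fibroblast and matrix genes tested, 2 fell and none rose over all probe sets, 3 were lower adjusted over the list alone, and 23 had a negative difference, with a median of -0.15. Camera gave an adjusted p = 0.00625, against an adjusted p = 0.688 with an estimated correlation and 0.262 with fry. The list: fibroblast and matrix markers also lost its call without WT replicate 2 (adjusted p = 0.0991) and without a variance trend (adjusted p = 0.0548), and Col1a2 lost its call without WT replicate 2 (adjusted p = 0.102). Type I collagen is abundant in bone as well, and the bone genes Ibsp, Dmp1 and Mmp13 fell on the same arrays.

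Pdia6, a protein disulfide isomerase, rose by 0.93 ± 0.15 (adjusted p = 0.00818), and Dnaja1, a co-chaperone (0.54 ± 0.13, adjusted p = 0.0671), and Hspa5, the main chaperone of the endoplasmic reticulum (0.38 ± 0.11, adjusted p = 0.111), were higher adjusted over the list alone. In heat shock and unfolded protein response, 1 of 24 tested genes rose over all probe sets, 3 were higher adjusted over the list alone, 19 had a positive difference, and the list's adjusted p was 0.0515 (0.688 with an estimated correlation). Meg3, a maternally expressed noncoding RNA, fell from 4008 and 4080 to 1816 and 1598 at 1439380_x_at (-1.25 ± 0.10, adjusted p = 1.02e-05), and Dlk1, its paternally expressed neighbour and a Notch-like growth regulator, fell by 0.58 ± 0.10 (adjusted p = 0.00905). Among 18 imprinted growth genes tested, these 2 fell over all probe sets and Cdkn1c, a growth-restraining kinase inhibitor, was the third lower member adjusted over the list alone (-0.40 ± 0.11, adjusted p = 0.111). The imprinted list did not pass as a whole (adjusted p = 0.449), and its median was 0.035 where its mean was -0.063. The skeletal muscle list moved the same way as Meg3 and Dlk1, by a median of -4.03, and whether they share a source was not tested. The Dlk1 call was lost without WT replicate 1 (adjusted p = 0.0529) and without WT replicate 2 (adjusted p = 0.0588).

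Among the genes of the cell cycle, Ccnd2, a D-type cyclin, fell by 0.48 ± 0.10 (adjusted p = 0.0374), and Ccnd3, another, was lower adjusted over the list alone (-0.47 ± 0.12, adjusted p = 0.0724). The other 48 of the 50 tested genes of cell cycle, replication and mitosis passed neither way, 31 of the 50 had a positive difference, and the list did not pass (adjusted p = 0.614). Cdkn1a, the p53-induced kinase inhibitor, was not past the threshold (-0.55 ± 0.16, adjusted p = 0.113). It was lower adjusted over the list alone together with Cdkn1c, Cdkn1b (-0.47 ± 0.16) and the p53 target Phlda3 (-0.56 ± 0.15), 4 of 15 tested kinase inhibitors and p53 targets, against 0 over all probe sets and 5 at unadjusted p under 0.05 (list adjusted p = 0.0818, and 0.688 with an estimated correlation). Ccnd2 lost its call without WT replicate 1 (adjusted p = 0.277) and without WT replicate 2 (adjusted p = 0.115).

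**Figure D4:**
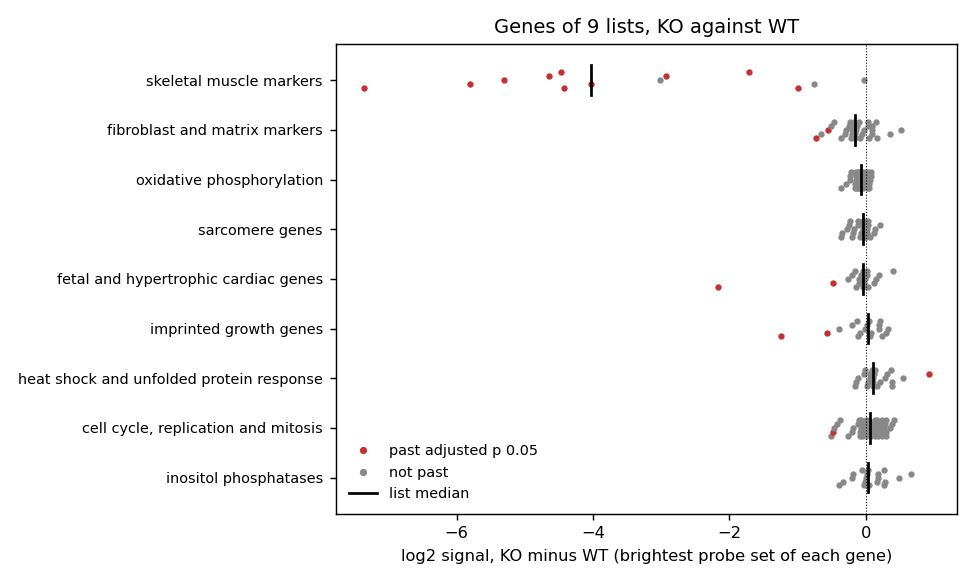
Difference in log2 signal (KO minus WT) of the brightest probe set of each tested gene in 9 lists, with red for genes past adjusted p 0.05, grey for the others and a black bar at each list's median. The skeletal muscle list has a median of -4.03, and the medians of fibroblast and matrix and of oxidative phosphorylation genes are -0.15 and -0.079.

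Among regulators of cardiac development 1 gene passed the test. Sfrp1, a secreted Wnt antagonist, rose by 0.70 ± 0.14 (adjusted p = 0.0207) and was the 1 called gene among 15 Wnt and beta-catenin targets tested, also adjusted over the list alone (list adjusted p = 0.920). No gene passed, over all probe sets or adjusted over the list alone, among 24 cardiac transcription factors (adjusted p = 0.449), with the coactivator Myocd at -0.48 ± 0.13 and 6 at unadjusted p under 0.05, or among 24 response genes of BMP, TGF-beta and Notch (adjusted p = 0.184), with Tgfb1 at -0.65 ± 0.17 and again 6. Of 19 immediate early genes (adjusted p = 0.813), 0 passed over all probe sets and 4 had an unadjusted p under 0.05, while Jund was higher (0.41 ± 0.10) and Ccn1 lower (-0.52 ± 0.15) adjusted over the list alone. The Sfrp1 call was lost without WT replicate 2 (adjusted p = 0.136).

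Markers of other heart cell types gave single calls. Plvap, a protein of endothelial diaphragms, fell by 0.81 ± 0.16 (adjusted p = 0.0223), the 1 called gene of 24 endothelial markers, also adjusted over the list alone (list adjusted p = 0.278). Sln was likewise the 1 called gene of 10 atrial markers (list adjusted p = 0.920), where Adm (0.62 ± 0.20) and Pam (0.29 ± 0.10) were higher and Sln lower adjusted over the list alone. No gene passed either way among 15 epicardial markers (adjusted p = 0.928, 0 at unadjusted p under 0.05) or 9 markers of the conduction system and trabeculae (adjusted p = 0.270, 2 at unadjusted p under 0.05). Plvap lost its call without WT replicate 1 (adjusted p = 0.166).

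Markers of tissues that a dissected ventricle could carry, apart from skeletal muscle, held 1 call in the lists fixed beforehand, which have none for bone. Hbb-y rose at its brightest probe set, 1436717_x_at (1.83 ± 0.39, adjusted p = 0.0376), and was the 1 called gene of 9 erythroid markers, also adjusted over the list alone (list adjusted p = 0.449). That call was lost without KO replicate 1 (adjusted p = 0.0710), KO replicate 2 (0.12) or WT replicate 2 (0.0982). No gene passed over all probe sets or adjusted over the list alone among 14 macrophage and leukocyte markers (adjusted p = 0.184), 11 genes of interferon and inflammation (0.449), 6 Schwann and neural crest markers (0.449) and 6 markers of brown and mediastinal fat (0.627), which held 3, 2, 1 and 1 genes at unadjusted p under 0.05. Of 8 REST-repressed and neuronal genes (adjusted p = 0.752), Gap43, with no Present call in WT, was higher adjusted over the list alone (at least 1.91-fold, adjusted p = 0.127). The lists of thymus and lymphocyte, lung and airway, and liver and yolk sac markers had 4, 3 and 1 genes tested, too few for a list test, and no gene past the threshold. Themis, a thymocyte gene and the 1 of these at unadjusted p under 0.05, was lower adjusted over its list alone, at least 3.07-fold (adjusted p = 0.160). Median, mean and direction of the list test were not all of 1 sign for PI3K, Akt and Gsk3 signalling, REST-repressed genes, Wnt targets, atrial markers, fatty acid oxidation, glycolysis and hypoxia response, and imprinted growth genes. Of the 31 lists tested, 3 passed with the preset correlation, 0 with an estimated correlation and 1, skeletal muscle, with fry. With an estimated correlation even the skeletal muscle list, with 10 of its 13 tested genes called, did not pass in camera (adjusted p = 0.346). The fetal cardiac list went from 0.0818 to 0.688 in camera although its estimated correlation, -0.013, was below the preset 0.01. That 0 therefore does not show that correlation between genes accounts for the other calls.

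Genes near Hdac2 on its chromosome were compared with the rest because the strain is mixed. Ddo, a D-aspartate oxidase, fell by 2.94 ± 0.21 at 1439096_at (adjusted p = 3.21e-06), and Cd24a, a surface glycoprotein, and Cd164, a sialomucin, rose by 0.74 ± 0.12 and 0.51 ± 0.11 (adjusted p = 0.00633 and 0.0343). With Hdac2, these were the 4 called genes of 110 within 20 Mb in assembly GRCm38.p6. Their mean absolute t was 1.57, against 1.26 over all genes, these and 10046 others (permutation p = 0.0204), and the difference rested on Hdac2 itself, since without it the mean was 1.33 against 1.26 (permutation p = 0.509). The share of nearby genes at unadjusted p under 0.01 was 6.36%, against 5.44% of all genes (permutation p = 0.669). The Cd164 call was lost without WT replicate 1 (adjusted p = 0.275) and without KO replicate 2 (adjusted p = 0.101).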

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

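The fits of the signal log ratio, the count from the brightest probe set of each gene, the count and lists without the listed muscle, bone, cartilage and tendon genes, and the share of nearby genes without Hdac2 were chosen only after the result was seen. The other settings were planned. Of 64 called probe sets followed through every setting, those named in the text among them, 41 stayed past the threshold with every array left out, 23 were lost with at least 1, 40 with no filter on detection, 47 with no variance trend and 1, of Ibsp, with another scaling or offset. Against 73 higher and 183 lower probe sets, there were 4 and 19 with no variance trend, 7 and 30 with no filter on detection, 48 to 222 and 110 to 428 with 1 array left out, and 54 and 96 with the brightest probe set of each gene, which tests fewer probe sets. Of the 256 calls, 36 remained with no filter and 23 with no variance trend, none with an opposite sign. The 64 were not a random draw from the 256, so the share of them that was kept does not stand for all calls. The signal log ratio gave 0 and 0, or 0 and 1 with its variance trend on the log2 signal. It is rounded to 0.1, 508 tested probe sets had no spread within the groups and the prior degrees of freedom were 1.2 in place of 11.5, but whether this accounts for the lost calls was not tested. Hdac2 transcript level, brightest probe set, stood at -5.40 in both fits (adjusted p = 0.0771 and 0.0797). In both, Rpl37a reversed to -0.40 and Ccnd1 to 0.05, and 4 of the 256 calls had the opposite sign. The exploratory counts (probe sets at p under 0.01 and 1.5-fold, higher in KO and probe sets at p under 0.01 and 1.5-fold, lower in KO) of 193 and 433 became 62 and 186 with an offset of 64, which shrinks folds of dim probe sets, 105 and 172 with the brightest probe sets, 111 and 255 or 90 and 196 with the signal log ratio, and 161 to 326 and 325 to 664 with 1 array left out.

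The gene lists past adjusted p 0.05, 3 in number, became 5 with quantile normalization, 6 when centred on the median, 5 with Present on all 4 arrays, 8 with the mean of a gene's probe sets, 4 to 5 with 1 array left out, 1 with no variance trend, 1 with fry and 0 with an estimated correlation. Heat shock and unfolded protein response was among those added under quantile normalization, centring, no filter and Present on all 4 arrays, and without WT replicate 1 or KO replicate 1. Sarcomere genes were added under centring, Present on all 4 arrays and the mean of probe sets and without KO replicate 2, and fetal and hypertrophic cardiac genes under centring and the mean of probe sets and without WT replicate 1, WT replicate 2 or KO replicate 2. Kinase inhibitors and p53 targets were added under quantile normalization, and the lists of cardiac transcription factors, of BMP, TGF-beta and Notch response and of imprinted growth genes under the mean of probe sets. The histone deacetylase list was added without WT replicate 1, WT replicate 2 or KO replicate 1. It holds Hdac2 itself and was not tested without it, so these calls say nothing about the other deacetylases. The medians are the same under the other list tests, with -4.03 for list: skeletal muscle markers (adjusted p = 0.346 with an estimated correlation), -0.079 for list: oxidative phosphorylation (0.701 with an estimated correlation, 0.378 with fry, 0.0701 with no variance trend) and -0.15 for list: fibroblast and matrix markers (0.688, 0.262 and 0.0548). With 1 array left out, oxidative phosphorylation ranged from -0.11 to -0.033 and fibroblast and matrix genes from -0.20 to -0.11. The genes near Hdac2 on its chromosome gave 1.33 without Hdac2 itself (permutation p = 0.509), 6.36% as a share (p = 0.669) and 5.50% as a share without Hdac2 (p = 1), and kept their call with windows of 10 Mb (permutation p = 0.00579) and 40 Mb (permutation p = 0.0139) that include it.

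Near 0, Ckm reversed to 0.023 with quantile normalization. Over the arrays left out, the values that reversed ranged from -0.084 to 0.028 for Ckm, -0.15 to 0.066 for Ccnd1, -0.24 to 0.084 for Hdac3, -0.052 to 0.69 for Hdac6 1448928_at, -0.37 to 0.0038 for Meg3 1436057_at, -0.092 to 0.013 for Myh7, -0.047 to 0.28 for Nppa and -0.11 to 0.056 for Nppb. Except where a reason is given, the cause was not tested. Hdac2 has no value under Present on all 4 arrays, as it is not Present in KO. The series' table of values and, for camera, the robust prior change nothing by construction.

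The title's number as a replicate block gave 271 higher and 450 lower probe sets and 6 lists, among them the heat shock, fetal cardiac and histone deacetylase lists, with Hdac2 at -5.66. The labels do not say that the number pairs the pools, and deviations of pools with the same number correlated at -0.011 over the tested probe sets, so the larger counts are not read as a pairing.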

Other observations

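The genes of the first paragraph, the test of signal loss away from the 3' end, the final test of a shift with brightness and the splits of the arrays were chosen only after the result was seen, and so were the markers of bone, cartilage, tendon, epidermis and muscle, whose own values had not been seen except those of 7 called genes and of Casq1, Perp and Pax7, members of lists fixed beforehand. Meg3 and Dlk1 are 2 of several genes of 1 imprinted cluster that fell. Rian and Mirg, maternally expressed noncoding RNAs of that cluster, fell too, Rian at least 3.56-fold at 1427580_a_at (adjusted p = 0.00199) and with a difference of -1.85 ± 0.26 at 1452899_at (adjusted p = 0.00207), and Mirg at least 2.06-fold (adjusted p = 0.0171), while Rian 1428055_at stood at -0.88 ± 0.31 (adjusted p = 0.192). Meg3 fell at 5 of its 7 tested probe sets, with differences of -0.81 to -1.51, and stood at -0.74 ± 0.34 and -0.18 ± 0.22 at the others. Whether the falls of this cluster share a source with that of the skeletal muscle list (median -4.03) was not tested. The Mirg call was lost without WT replicate 1 (adjusted p = 0.0614) and without WT replicate 2 (adjusted p = 0.0732), and that of Meg3 at 1452905_at without KO replicate 2. Hspb7, a small heat shock protein of heart and skeletal muscle, fell at all 3 of its tested probe sets, with differences of -2.04 ± 0.23, -1.11 ± 0.10 and -0.91 ± 0.12 (adjusted p = 0.000295, 5.13e-05 and 0.00196). Ctsk, the bone-resorbing protease cathepsin K, fell by 1.08 ± 0.21 (adjusted p = 0.0206), a call lost without WT replicate 1 (adjusted p = 0.084). Of the added markers detected in WT and not seen before, 1 of 2 for bone (Ctsk) fell, and 0 of 2 for muscle, 5 for cartilage, 3 for tendon and 3 for epidermis passed in limma, with Sypl2 of muscle (-0.79 ± 0.19, adjusted p = 0.0661) and Col9a1, Hapln1 and Thbs4 at unadjusted p under 0.05.

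Skeletal muscle genes and the bone genes Ibsp, Dmp1 and Mmp13 were lower in KO, and loss of signal away from the 3' end is argued against, since the muscle list fell by 3.40 log2 units more than the largest fall of a 5' over 3' control ratio (actin, -0.32). Tissue from outside the heart in the WT pools may be a source. It predicted a median under -1 over cartilage and tendon markers detected in WT, but the 8 measured had a median of -0.27 (95% bootstrap interval -0.91 to 0.61), short of the prediction and just past the bound of -0.3 set against it, though not by more than the spread, a condition added after the value was seen, as all 5 cartilage markers lay below 0 (Col9a1 at -0.91, Hapln1 at least 2.68-fold lower, with no Present call in KO) and all 3 tendon markers above it at their brightest probe set (Thbs4 at 0.61). All 3 tendon markers, Col9a1 and Ihh were Present on both KO arrays, Acan was Present on 1, and Hapln1 and Snorc on none. Signal from the KO pools themselves could mask a fall in the markers still Present there, which limits the test. Lower expression in KO heart muscle alone required bone markers above -0.3, and the 2 not seen before had a median of -0.64 (Sp7 at -0.20, Ctsk at -1.08), too few to decide. The 2 explanations cannot be told apart with these markers, and an effect of genotype on several tissues stays open, as untested. The 3 epidermis markers not seen before had a median of -0.18 and the 2 further muscle markers one of -0.59. Of the 7 added muscle markers detected in WT, 4 were called lower, all seen before, while Casq1, also seen before, stood at 0.31 ± 0.11 (adjusted p = 0.209 in limma).

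Xist rose and the Y-linked genes Eif2s3y and Uty fell in KO. Xist 1427262_at had no Present call in WT (1.3 and 6.1) and read 414 and 797 in KO, though 1436936_s_at was Present on both WT arrays. KO replicate 2 had more Xist and less Eif2s3y (126 against 240) than KO replicate 1. A different sex of the pooled embryos and an effect of genotype on these genes both stay open, as untested, since these values are the pattern itself and the sources used here do not give the sex of any embryo. If the mix of sexes differs between the groups, its effects cannot be told apart from those of genotype in any call here.

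Of 155 called probe sets of genes with at least 2 tested, 74 belonged to genes whose brightest probe set did not pass, as for Akt1, Myh6, Serinc3 and Rpl37a, and 60 of the 74 were lower. Shorter labelled RNA in KO may contribute, because the dimmest minus the brightest probe set of a gene had a median of -0.082 (95% bootstrap interval -0.093 to -0.067) as it predicted. The mean actin and Gapdh 3' over 5' ratios were also higher in KO (2.58 against 2.08 and 1.09 against 0.90). Among genes with 1 probe set, dim ones differed as much from bright ones (-0.11). Where their probe sets lie is not known, so the test cannot separate shorter RNA from a shift with brightness. The calls lower in KO among the 74 had a median difference of -0.96, far larger than either -0.082 or -0.11. The test first written, on that -0.11, came out for a shift with brightness, but this is argued against as the whole cause, since 58 of the 74 calls stayed past the threshold after quantile normalization. Probe sets ending in _x_at or _s_at made up 20.3% of the 74 and 19.5% of the others (Fisher's exact test, one-sided p = 0.478), which leaves cross-hybridisation open, a reading loosened after the value was seen. Separate transcripts of 1 gene that respond differently to genotype stay open, as untested.

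The 4 arrays can be split into pairs in 3 ways, too few for a share under 0.05: the real split, the 1 with as many calls, gave 256 probe sets and the highest of the other splits 0.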
